A study of Mus musculus with 2 samples.

How the data were processed

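The deposited files are 10x Genomics gene by barcode matrices of whole UMI counts, per the file headers, for 2 lung libraries, 1 from mice given IgG and 1 from mice given the S100A4-11 antibody, on day 14. Per the labels' protocols, dissociated tissue was captured with the 10x Genomics 5' chemistry and sequenced on a DNBseq instrument. The protocol text calls the tissue tumour, while the titles, source and tissue labels say lung; the libraries held alveolar and other lung cell classes and were read as lung. Per the submitters' processing notes, reads were processed with Cell Ranger 7.1.0 and build mm10. The number of animals behind each library is not stated in the labels. The IgG matrix held 14411 barcodes and 85458143 UMIs (median 4140 UMIs and 1616 genes per barcode), and the S100A4-11 matrix 12506 barcodes and 64695542 UMIs (3755 and 1485), over 32286 features. Every deposited barcode held at least 500 UMIs. A gene whose symbol occurred more than once kept the symbol for the feature with the most UMIs.

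Barcodes with under 200 genes (67 IgG, 101 S100A4-11) or over 15% mitochondrial UMIs (66 and 46) were removed. Doublets were called in each library by Scrublet in Scanpy 1.11.5 at its automatic threshold, which removed 1000 (7.00%) and 690 (5.58%) cells. This left 13285 and 11675 cells, with 74878834 and 58136849 UMIs and median depths of 3962 and 3637 UMIs. Both libraries were clustered together without integration: counts scaled and log-transformed, 2000 variable genes ranked within each library, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). Mitochondrial, ribosomal protein, haemoglobin and antigen receptor variable-segment genes were kept out of the variable genes. No correction for free RNA was made.

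Clusters were named from markers of 25 cell classes. A cluster took the class with the largest share of markers found in at least 25% of its cells at 2-fold the mean of other cells, with at least 3 such markers. Within a lineage the class with most of the 10 leading genes was taken. A cluster stayed unnamed where genes of another class led. It also did where markers of a class of another lineage were detected at a median of at least 50% of their highest rate in any cluster. A further rule, for very shallow clusters in which no marker led, left no cluster unnamed at Leiden resolution 1. The markers, 25 gene lists, named genes rule and most alternatives were fixed before the data were examined; the exact naming rule was set after the clusters had been seen. Cell classes are called by name with "-like" because they rest on transcripts alone, and their markers are not reported as results.

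Shares were compared over all kept cells and over immune classes, with exact binomial intervals for each share and an exact conditional interval for the ratio. Within a class with at least 100 cells in each library (13 classes), UMIs were summed over cells and given per 1000000 UMIs of the class (CPM). Each level had an exact Poisson interval and each ratio an exact conditional binomial interval. With 1 library per group no test was made, and no p-value, standard error or count of changed genes is given. In each class, and in all cells, genes were named that had at least 50 CPM and at least 50 UMIs in 1 library and at least 20% of the highest CPM of any named class. Mitochondrial, ribosomal protein, haemoglobin and variable-segment genes were not named. Genes were ranked by the interval bound nearest a ratio of 1. The 10 highest and 10 lowest were named in endothelial-like and neutrophil-like cells, 6 each in B cell-like, fibroblast-like and T cell-like cells, and 3 each elsewhere. S100a4 and, from each list, the 4 expressed members with the largest bound were added, of which examples are given. A gene was called higher or lower only at a ratio of at least 1.5 with an interval excluding 1.

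For a gene list, the median log2 ratio of members with at least 20 UMIs (pseudocount 0.5) was set against 10000 random lists of the same size, matched in 20 expression bins, as a description of these libraries. The 25 lists were read in classes fixed for each, which gave 60 pairs of list and class. Readings planned for dendritic cell-like cells were left out because at Leiden resolution 1 no cluster took that name. S100a4 was also read as the share of cells with a UMI, before and after thinning every cell to 500 UMIs. Gene positions were looked up by gene ID in the GENCODE M21 annotation of GRCm38; 107 of 108 named genes were found, with S100a4 on chromosome 3 at 90603771 to 90606045 on the plus strand.

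Alternatives were: every barcode kept, at least 500 genes, doublets kept, Leiden resolutions 0.5 and 2, each library clustered alone, genes scaled within each library, and immune cells only. For expression and lists they were median-of-ratios scaling, TMM scaling (edgeR 4.0.16 in R 4.3.3), totals without mitochondrial, ribosomal protein and haemoglobin genes, every cell weighing the same, doublets kept and at least 500 genes. For lists they also were no filter on low counts and at least 100 UMIs. Leaving out unnamed clusters, and Leiden resolution 2 for the lists and genes of interstitial macrophage-like cells, were added after seeing the data. The comparison was tested on simulated data before use, for its recovery of known folds and the coverage of its intervals. Of 100 unchanged lists, 7 in endothelial-like and 4 in neutrophil-like cells lay outside the middle 95% of random lists. Counts were drawn as independent Poisson values, which the intervals also assume, so UMIs held by few cells were not tested. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.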

Results

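Lungs of BALB/c mice carrying 4T1 mammary fat pad tumours were compared on day 14 after inoculation, between mice given IgG and mice given the S100A4-11 antibody. Each group had 1 library, so differences between the libraries had no replicate check. Intervals in parentheses are exact 95% counting intervals and cover counting error only; folds are S100A4-11 over IgG unless a gene is called lower. After filtering and removal of doublets, 13285 IgG cells and 11675 S100A4-11 cells remained, in 38 clusters. Fixed markers named 18 cell classes, and 6 clusters stayed unnamed, with 8.34% of IgG cells and 6.27% of S100A4-11 cells. No cluster was carcinoma-like, and no cluster was named dendritic cell-like at Leiden resolution 1. At resolution 2 the interstitial macrophage-like class split into 250 interstitial macrophage-like and 222 dendritic cell-like cells, so its values mix both types.

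B cell-like and NK cell-like cells made up a larger share of the S100A4-11 library, and stromal and alveolar epithelial classes a smaller share. B cell-like cells were 6.43% (6.02 to 6.86) of IgG cells and 11.5% (10.9 to 12.1) of S100A4-11 cells, a fold of 1.79 (1.64 to 1.95). NK cell-like cells were 3.24% (2.95 to 3.56) and 4.97% (4.58 to 5.38), a fold of 1.53 (1.35 to 1.74). Pericyte or smooth muscle cell-like cells were 3.99% and 2.41% (fold 0.603, 0.520 to 0.699), and type 2 alveolar epithelial-like cells 2.17% and 1.39% (0.640, 0.525 to 0.779). Type 1 alveolar epithelial-like cells were 144 and 46 cells (0.363, 0.255 to 0.510). Neutrophil-like cells, whose recruitment to the lung is widely studied in this tumour model, were 17.6% of both libraries (fold 1.0, 0.942 to 1.06).

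Other folds were 1.23 (1.12 to 1.36) for T cell-like, 1.26 (1.12 to 1.42) for classical and 1.41 (1.22 to 1.63) for nonclassical monocyte-like cells. They were 0.932 (0.885 to 0.981) for endothelial-like, 0.804 (0.734 to 0.881) for fibroblast-like and 0.793 (0.706 to 0.891) for alveolar macrophage-like cells. Interstitial macrophage-like cells had a fold of 0.909 (0.754 to 1.09) and immature granulocyte-like cells 0.868 (0.742 to 1.01). Small classes were innate lymphoid or gamma-delta T cell-like (0.688, 0.507 to 0.930), basophil or mast cell-like (1.29, 0.848 to 1.96), lymphatic endothelial-like (1.14, 0.681 to 1.90) and airway epithelial-like cells (0.683, 0.358 to 1.27). With each library clustered alone, more folds moved outside their intervals. The fold was then 1.84 for immature granulocyte-like, 0.452 for interstitial macrophage-like, 0.972 for fibroblast-like and 0.866 for neutrophil-like cells. For classical and nonclassical monocyte-like cells it was 1.12 and 1.65. Immune classes together were 51.3% and 59.8% of cells. Among immune cells alone, the fold was 1.53 (1.41 to 1.67) for B cell-like, 1.31 (1.16 to 1.49) for NK cell-like and 0.858 (0.808 to 0.911) for neutrophil-like cells. Shares also depend on how well each cell type survives dissociation and capture, which can differ between preparations. An unnamed cluster with epithelial and endothelial genes held 257 IgG cells and 23 S100A4-11 cells and may be a feature of the IgG library. Its cells differed between the libraries, with median depths of 2308 and 17355 UMIs. Col1a1 was found in 36.6% and 78.3% of them, and Ptprc in 30.4% and 4.35%. Type 2 alveolar markers led this cluster, but it was not counted in the alveolar epithelial shares.

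**Figure D1:**
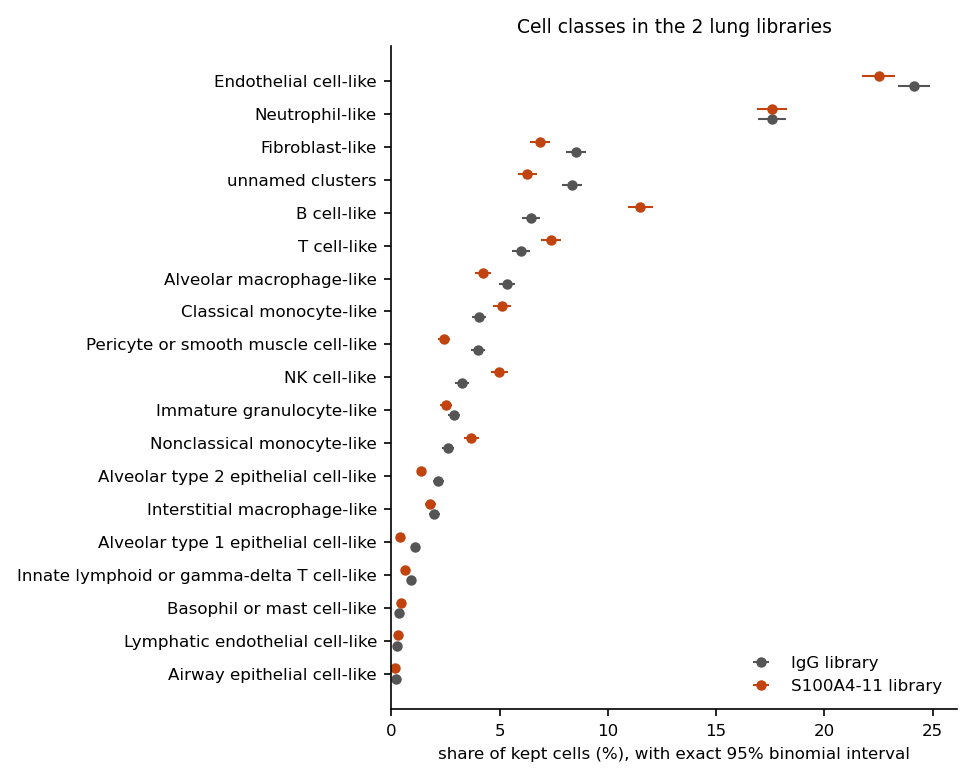
Shares of kept cells by cell class in the IgG and S100A4-11 libraries. Bars are exact 95% binomial intervals and cover counting error only; each group has 1 library.

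S100a4, which encodes the antibody's target, was highest in innate lymphoid or gamma-delta T cell-like cells and classical monocyte-like cells. In these it reached 1183 and 1232 CPM (UMIs of the gene per 1000000 UMIs of the class) and 866 and 889 CPM in the IgG and S100A4-11 libraries, folds of 1.04 (0.905 to 1.20) and 1.03 (0.986 to 1.07). Nonclassical monocyte-like cells held 260 and 337 CPM, interstitial macrophage-like cells 247 and 220 CPM and T cell-like cells 204 and 212 CPM. Pericyte or smooth muscle cell-like cells held 139 and 152 CPM, NK cell-like cells 68.8 and 57.7 CPM, and fibroblast-like cells 25.4 and 23.6 CPM. Over all cells S100a4 was at 108 and 134 CPM (fold 1.24, 1.20 to 1.28), in libraries that differed in cell mix. An antibody to the protein need not alter the transcript, so these values do not test the treatment.

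At least 1 S100a4 UMI was found in 94.96% of IgG and 96.1% of S100A4-11 classical monocyte-like cells, with median depths of 10155 and 8975 UMIs. After every cell was thinned to 500 UMIs the shares were 33.0% and 33.4%. In T cell-like cells the shares were 14.8% and 18.9% (5.93% and 7.22% after thinning). In neutrophil-like cells, a type with little S100a4, the shares were 0.599% and 0.487%, with median depths of 3755 and 3551 UMIs and levels of 2.76 and 2.56 CPM. Levels in immature granulocyte-like (3.36 and 4.66 CPM), endothelial-like (3.58 and 6.45 CPM), B cell-like (13.5 and 7.92 CPM), alveolar macrophage-like (12.6 and 7.93 CPM) and type 2 alveolar epithelial-like cells (4.87 and 12.4 CPM) were low too. With doublets kept, the B cell-like, type 2 alveolar epithelial-like, neutrophil-like, fibroblast-like and T cell-like ratios changed sign, and the immature granulocyte-like and endothelial-like ratios moved outside their intervals.

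**Figure D2:**
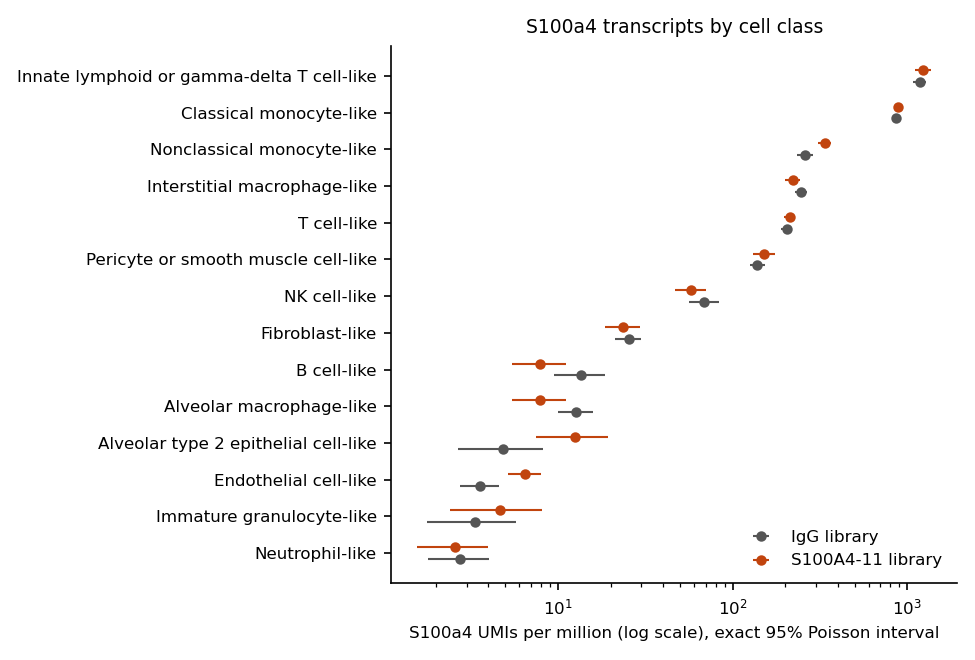
S100a4 by cell class, as CPM of the class. Bars are exact 95% Poisson intervals and cover counting error only.

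In endothelial-like cells, genes of the interferon-gamma response and MHC class I presentation lay below random lists in the S100A4-11 library. All 21 measured members of that list had a log2 ratio below 0, not all past 1.5-fold, with a median log2 ratio of -0.47, at percentile 0 of 10000 matched random lists as a description of these libraries. Gbp4 and Igtp, interferon-induced GTPases, were 1.53-fold (1.46 to 1.61) and 1.55-fold (1.40 to 1.73) lower. Tap1, which moves peptides to MHC class I, was at 77.1 and 51.9 CPM, and the transcription factor Irf1 at 400 and 286 CPM. Dissociation stress genes, which respond to tissue handling, lay below random lists in the same cells, with a median of -0.48 at percentile 0 over 18 members. Fosb, Egr1 and Dusp1, immediate early genes, were 2.60-fold (2.37 to 2.86), 1.68-fold (1.60 to 1.78) and 1.57-fold (1.51 to 1.62) lower, each at under 20% of its level in the class where it was highest.

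Lower genes in endothelial-like cells also included stress-linked Hsph1 (2.53-fold, 2.34 to 2.73), Atf3 (1.94-fold, 1.85 to 2.03) and Hspb1 (1.68-fold, 1.63 to 1.72), the first and last of these encoding heat shock proteins. Zbtb16, a transcription factor, was 2.05-fold (1.96 to 2.15) lower, Adamts9, a secreted protease, 2.0-fold (1.88 to 2.12), and Sgms1, a sphingomyelin synthase, 1.69-fold (1.60 to 1.78). Gm47283 (2.82-fold), Arhgap28 (1.99-fold), Glis3 (1.85-fold) and Adgrl3 (1.62-fold) were lower too. Adgrl3 was the leading gene of cluster 8, which held 20.9% of endothelial-like cells in the IgG library and 14.9% in the S100A4-11 library, so cluster mix enters its ratio. Ndufb1-ps (1.53-fold), Pet100 (1.52-fold), an assembly factor of cytochrome oxidase, and the RNA polymerase subunit Polr2l (1.52-fold) were higher. Folds were 1.40 for AY036118, 1.44 for Cd200, 1.45 for Atp5k, 1.38 for Il31ra, 1.35 for Cdk8 and 1.38 for Zc3h7a. The activation and adhesion list had a median of 0.11 (percentile 99.2, or 69.8 with every cell weighing the same), with Vwf, a clotting and adhesion protein, at 260 and 311 CPM but the adhesion receptor Icam1 at 429 and 309 CPM. Angiogenesis genes had a median of 0.00 (percentile 60.7) and type I interferon response genes -0.01 (percentile 50.3, or 2.10 with every cell weighing the same).

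In neutrophil-like cells, type I interferon response genes lay below random lists in the S100A4-11 library. All 19 measured members had a log2 ratio below 0, not all past 1.5-fold, with a median log2 ratio of -0.39 (percentile 0). Zbp1, a sensor of nucleic acids, was 1.93-fold (1.67 to 2.24) lower, and Ifit1, an antiviral protein, 1.77-fold (1.54 to 2.04). Rsad2, also antiviral, was at 122 and 92.6 CPM. The interferon-induced GTPases Gbp2, Gbp2b and Gbp7 were 1.68-fold (1.59 to 1.77), 1.62-fold (1.40 to 1.88) and 1.57-fold (1.38 to 1.79) lower, and Parp14 1.55-fold (1.36 to 1.76).

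Cxcl3, a neutrophil-attracting chemokine, was 1.97-fold (1.89 to 2.05) lower, Saa3, an acute phase protein, 1.59-fold (1.49 to 1.71), and Plin2, a lipid droplet protein, 1.55-fold (1.48 to 1.62). Higher genes were Cpne8 (1.65-fold, 1.44 to 1.90) and the linker histone gene Hist1h1c (1.55-fold, 1.35 to 1.80). Ptgs2, a prostaglandin synthase, was at 1202 and 1552 CPM, Il1b at 22899.7 and 26005 CPM, S100a8 at 44258 and 42461 CPM and S100a9 at 75759 and 71608 CPM. Hypoxia and glycolysis genes had a median of -0.10 (percentile 0.415, or 6.09 with every cell weighing the same), with the enzymes Pgam1 at 168 and 138 CPM and Ldha at 494 and 444 CPM. Medians within the range of random lists were -0.08 for the S100 family, -0.08 for granule genes, -0.02 for suppressive genes and 0.05 for inflammatory and NF-kB genes; with at least 500 genes per cell, granule genes were at percentile 0.560 and NF-kB genes at 99.1. They were 0.04 for dissociation stress, 0.19 for proliferation (4 genes) and -0.05 for chemokine receptors and homing.

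In classical monocyte-like cells of the S100A4-11 library several inflammatory and interferon genes were lower. Saa3 was 2.78-fold (2.58 to 3.0) lower, Areg, a growth factor of epithelial cells, 2.5-fold (2.26 to 2.76), and Mmp19, a metalloprotease, 2.23-fold (1.90 to 2.64). Cxcl1, a neutrophil-attracting chemokine, was 1.57-fold (1.49 to 1.66) lower and Gbp3 1.54-fold (1.27 to 1.86). Type I interferon genes had a median log2 ratio of -0.35 (percentile 0), with 20 of 21 members below 0, and the interferon-gamma and MHC class I list -0.18 (percentile 0.080). Suppressive genes had a median of -0.26 (percentile 0), inflammatory and NF-kB genes -0.14 (percentile 0.150) and hypoxia and glycolysis genes -0.16 (percentile 0.120). With every cell weighing the same, the last pair were at percentiles 6.73 and 3.43. The S100 family (-0.06), factors reported to respond to extracellular S100A4 (-0.10) and MHC class II genes (0.02) lay within the range of random lists. The S100 family was below it without a filter on low counts (percentile 0.780) and with at least 100 UMIs per gene (0.04). With every cell weighing the same, the S100A4 factors (percentile 1.36, or 2.08 with doublets kept) and MHC class II genes (-0.16, percentile 0.370) were below it. Gm11808 was 1.77-fold higher, and the stress genes Hspa1b and Jun each had a fold of 1.49. The dissociation stress list, read in these cells after the result was seen, had a median of 0.16 (percentile 100).

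Nonclassical monocyte-like cells had lower Fkbp5, a glucocorticoid-induced immunophilin (2.90-fold, 1.85 to 4.67), Smpdl3b (1.83-fold) and Ddit4, a stress-induced gene (1.76-fold), and higher Il31ra (2.14-fold) and Gphn (1.82-fold). In immature granulocyte-like cells Nos2, the inducible nitric oxide synthase, was 2.86-fold (2.10 to 3.94) lower and the interferon-induced Ifitm1 1.58-fold (1.54 to 1.61). Fos (1.66-fold, 1.55 to 1.76) and Nr4a3 (1.83-fold, 1.52 to 2.21), both immediate early genes, were higher there. Prtn3, a granule protease, was 23.9-fold lower (13.2 to 48.3), but 1 IgG cell held 91.9% of its IgG UMIs.

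In T cell-like cells the regulatory T cell and proliferation lists lay above random lists in the S100A4-11 library. The regulatory list had a median log2 ratio of 0.43 (percentile 100), with Foxp3, the lineage's transcription factor, at 52.0 and 72.4 CPM and the inhibitory receptor Ctla4 at 217 and 319 CPM. Cluster 14, with Foxp3 and Ctla4 among its leading genes, held 28.5% of the class in the IgG library and 32.2% in the S100A4-11 library, so cluster mix enters this list. The proliferation list had a median of 0.59 (percentile 100); Ube2c was 1.74-fold (1.37 to 2.23) higher and Top2a, a topoisomerase of dividing cells, 1.69-fold (1.35 to 2.12), and 5 cells held 60.7% and 54.9% of the Top2a UMIs. Naive and memory genes had a median of -0.11 (percentile 0.060, or 7.1 with doublets kept), with the transcriptional repressor Bach2 at 521 and 389 CPM. Cytotoxic genes had a median of -0.30 (percentile 0, or 7.81 with every cell weighing the same). The granzyme Gzma was 3.71-fold (3.04 to 4.54) lower, at 128 and 34.6 CPM, far below its 11176 and 11471 CPM in NK cell-like cells, and 5 cells held 73.9% and 76.3% of its UMIs. Checkpoint genes (0.11), chemokine receptors (0.09), type I interferon genes (0.04), the interferon-gamma list (-0.04) and the S100 family (0.07) lay within the range of random lists. With doublets kept, the S100 family was at -0.15 (percentile 0.340), checkpoint genes at percentile 99.7 and chemokine receptors at 99.3. The S100 family was at 0.13 (percentile 98.5) with at least 100 UMIs per gene. Dissociation stress genes were at 0.08 (percentile 98.7, or 92.4 with at least 500 genes per cell). Hist1h2ae (1.99-fold), Cpne8 (1.76-fold), Tent5a (1.85-fold) and the cell cycle phosphatase Cdc25b (1.68-fold) were higher, and Fam169b (1.62-fold), Maff (1.52-fold) and Gm47283 (2.10-fold) lower.

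NK cell-like cells had higher Xcl1, a chemokine that attracts dendritic cells (1.64-fold, 1.33 to 2.04), Hspa1b (1.58-fold) and Zfpm1 (1.87-fold), and lower Lpp (1.77-fold) and Ctla2a (1.57-fold). Hist1h1b was 4.39-fold lower (2.80 to 7.13), with 69.9% of its IgG UMIs in 1 cell. Their cytotoxic genes had a median log2 ratio of 0.07 (percentile 80.0). In B cell-like cells activation and class switch genes had a median of 0.13 (percentile 99.96, or 96.8 with doublets kept), with Nr4a1 at 1678 and 2060 CPM. Igha, the IgA heavy chain gene, was at 1.82 and 67.6 CPM, with 99.6% of its S100A4-11 UMIs in 1 cell. Cpne8 (2.10-fold, 1.62 to 2.75) and Gm11808 (1.92-fold, 1.62 to 2.28) were higher, and Zyg11b (1.66-fold), Ptpn22, a phosphatase of antigen receptor signalling (1.62-fold), Itgav (1.62-fold), Gigyf2 (1.67-fold) and Gm47283 (1.80-fold) lower. Their MHC class II (0.04), chemokine receptor (0.05), proliferation (0.05) and type I interferon (-0.23, percentile 4.61) lists lay within the range of random lists. With doublets kept, type I interferon genes were below it, at -0.47 (percentile 0.01). MHC class II genes were at percentile 98.7 with every cell weighing the same, and chemokine receptors at 98.3 with at least 100 UMIs per gene. Dissociation stress genes were at 0.09 (percentile 99.98), and a part of tissue handling in the activation genes was not tested.

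In fibroblast-like cells extracellular matrix genes lay below random lists in the S100A4-11 library. The matrix and remodelling list had a median log2 ratio of -0.15 (percentile 0.720, or 7.87 with doublets kept), with 23 of 27 members below 0. The mix of fibroblast clusters differed as well. Cluster 25, with Dcn and Col1a1 among its leading genes, held 16.2% of the class in the IgG library and 12.0% in the S100A4-11 library. Cluster 20, with Hs6st3 and Nebl among its leading genes, held 21.02% and 16.6%, with median depths of 2651.5 and 1553 UMIs. The shallow cluster 22 held 15.3% and 18.1%. Cluster mix may enter the list medians and gene ratios of this class, which was not tested. Eln, which encodes elastin, was 1.71-fold (1.57 to 1.87) lower, and the collagens Col14a1 and Col3a1 were at 374 and 268 CPM and at 1621 and 1301 CPM. The activation and inflammation list had a median of -0.15 (percentile 5.38). Its member Acta2, a smooth muscle actin, was 1.74-fold (1.59 to 1.91) lower, but at 333 and 192 CPM against 4320 and 3718 CPM in pericyte or smooth muscle cell-like cells, so free RNA of those cells was not excluded. Prkca (1.75-fold), the cholesterol exporter Abca1 (1.80-fold), Itgbl1 (1.85-fold), Hsph1 (1.89-fold) and A230057D06Rik (2.09-fold) were lower, as was Clu (2.10-fold), with 44.8% of its IgG UMIs in 1 cell. Polr2l (1.91-fold), Ier5l (1.73-fold) and Adm, a vasodilator peptide (1.70-fold), were higher. The S100 family (0.04), factors reported to respond to extracellular S100A4 (-0.16) and dissociation stress (-0.03) lay within the range of random lists; the S100A4 factors were below it with every cell weighing the same (percentile 1.42), with doublets kept (1.57) and with at least 100 UMIs per gene (1.5). S100a8 and S100a9 were 3.01-fold and 2.53-fold higher, but at 424 and 699 CPM against 42461 and 71608 CPM in neutrophil-like cells of the S100A4-11 library. In the IgG and S100A4-11 libraries, 5 cells held 51.2% and 53.9% of the S100a8 UMIs and 54.2% and 50.2% of the S100a9 UMIs. Both ratios changed sign when doublets were kept.

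Pericyte or smooth muscle cell-like cells had lower Tmem252 (2.21-fold, 1.90 to 2.59), Cpe, a prohormone-processing enzyme (2.99-fold, 2.13 to 4.30), and Gm47283 (2.76-fold), and higher Cdk8 (1.75-fold) and Gm34804 (2.05-fold). Tmem252 and Cpe were among the leading genes of endothelial-like clusters. In cluster 17 endothelial markers were detected at a median of 0.339 of their highest rate in any cluster, against 0.113 in cluster 21. This class lay mostly in cluster 17 in the IgG library (57.4%) and in cluster 21 in the S100A4-11 library (51.2%). Type 2 alveolar epithelial-like cells had higher Fdps, an enzyme of isoprenoid and sterol synthesis (1.64-fold, 1.41 to 1.91). Their Retnla was 8.67-fold higher (6.65 to 11.4), with 94.2% of S100A4-11 UMIs in 5 cells. Their airway genes Scgb3a2 (at least 103-fold lower, against a floor of 3 counts per library), Scgb1a1 (8.07-fold lower) and Cyp2f2 (3.05-fold lower) drew 83.4%, 61.0% and 44.6% of their IgG UMIs from 1 cell each.

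Alveolar macrophage-like cells of the S100A4-11 library had lower proliferation genes Ube2c (2.65-fold, 2.09 to 3.39) and Mki67 (1.85-fold, 1.54 to 2.25) and lower Fkbp5 (1.82-fold, 1.47 to 2.26). Pde1c (1.96-fold), Nkain2 (1.87-fold) and Peak1 (1.63-fold) were higher. Inflammatory and NF-kB genes had a median log2 ratio of -0.11 (percentile 0.290), with the cytokine Il1a at 346 and 274 CPM, and complement, scavenger and repair genes 0.04 (percentile 93.2). Without a filter on low counts the latter were at -0.17 (percentile 1.12). Dissociation stress genes, read in these cells after the result was seen, were at -0.14 (percentile 0). In interstitial macrophage-like cells complement, scavenger and repair genes had a median of -0.25 (percentile 0.020). Mertk, a receptor for dying cells, was 1.68-fold (1.23 to 2.33) lower. MHC class II genes were at -0.18 (percentile 0.5) and inflammatory and NF-kB genes at 0.09 (percentile 99.3). With every cell weighing the same they were at -0.12 (percentile 9.42) and -0.21 (percentile 0.1), in that order. At Leiden resolution 2, chosen for these lists after seeing the data, complement, scavenger and repair genes were at -0.049 (percentile 37.0) and MHC class II genes at 0.0063 (percentile 69.7), both within the range of random lists, and NF-kB genes at 0.22 (percentile 100). Spp1 (2.43-fold lower), Retnla (99.3-fold lower) and Il12b (2.06-fold lower) drew 85.4%, 100% and 86.5% of their IgG UMIs from 5 cells. At Leiden resolution 2 the direction of Il12b turned, to a log2 ratio of 2.51. Saa3, Prg4 and Alox15 were at 0 in the IgG library and at least 149-fold, 125-fold and 64.8-fold higher against a floor of 3 counts per library, all from 2 to 4 cells.

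**Figure D3:**
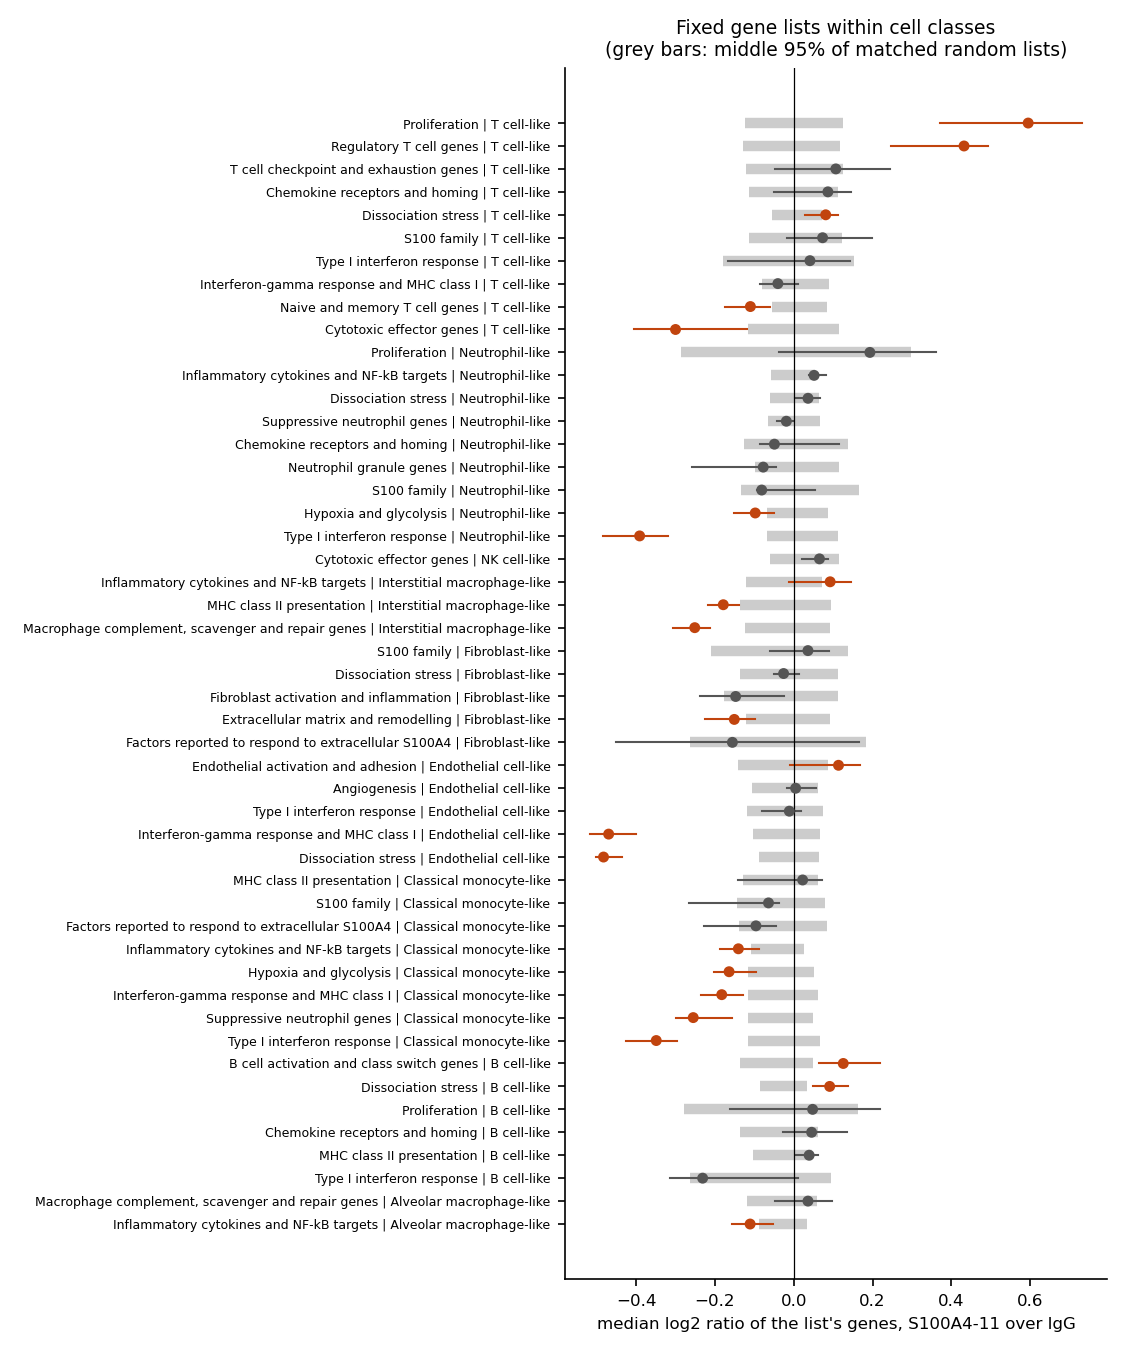
Median log2 ratios of fixed gene lists within cell classes. Grey bars mark the middle 95% of 10000 matched random lists, and coloured points lie outside it.

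Over all cells together, pre-metastatic niche factors had a median log2 ratio of -0.13 (percentile 0.900, or 4.64 with every cell weighing the same). The matrix protein gene Postn was 1.88-fold (1.78 to 1.99) and Saa3 1.63-fold (1.55 to 1.71) lower, while Ptgs2 was at 244 and 312 CPM. Cluster 17, with Postn among its leading genes, held 2.29% of IgG and 1.17% of S100A4-11 cells, so cell mix enters the Postn ratio. Proliferation genes had a median of -0.34 (percentile 0.020). Factors reported to respond to extracellular S100A4 (0.01), the S100 family (-0.08) and dissociation stress genes (0.01) lay within the range of random lists. Haemoglobin genes had a median of 0.84 (percentile 100), and were at 2.05 in B cell-like and 0.03 in T cell-like cells. In B cell-like cells 5 cells held 91.2% and 92.1% of the Hbb-bs UMIs. In T cell-like cells the median was 0.71 with every cell weighing the same and -1.37 with doublets kept. Surfactant and club cell genes had a median of -0.71 (percentile 0.010), -1.08 in B cell-like and -1.66 in T cell-like cells, both types that do not make them. Scgb1a1, the main club cell product, was 32.4-fold (31.2 to 33.6) lower, with a UMI in 5535 IgG cells and 466 S100A4-11 cells, so free RNA differed between the libraries. Fcmr (1.99-fold) and Cd79a (1.87-fold), both B cell genes, and Gm11808 (1.92-fold) were higher, and Zbtb16 (2.16-fold) and Nebl (2.02-fold) lower; these values mix the share of each class with its expression.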

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

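Leaving out unnamed clusters, and Leiden resolution 2 for interstitial macrophage-like cells, were chosen after seeing the data. No paired analysis was possible because each group had 1 library. Of class share folds under the alternatives fixed beforehand, 125 stayed within the interval of the reported fold and 19 moved outside it, and no share with a fold past 1.5 in either direction changed direction, while 6 folds in all crossed 1; all 19 folds without unnamed clusters stayed. Of list medians, 405 stayed, 71 moved and 1 that lay outside random lists changed sign. Of gene ratios, 1782 stayed, 285 moved and 9 called higher or lower changed sign. Of differences in S100a4 cell shares, 38 stayed and 3 moved. Counting values near 0 as well, 27 list medians, 31 gene ratios and 8 differences in S100a4 cell shares changed sign. Of the 29 list readings outside the middle 95% of random lists, 17 stayed outside under every fixed alternative run, among them type I interferon in neutrophil-like and classical monocyte-like cells and interferon-gamma in endothelial-like cells. Of the other 12, NF-kB genes in interstitial macrophage-like cells passed to the opposite side, at percentile 0.1 with every cell weighing the same. The rest were inside the range under some, such as matrix genes in fibroblast-like cells at percentile 7.87 with doublets kept and cytotoxic genes in T cell-like cells at 7.81 with every cell weighing the same. Of the 31 readings inside that range, 15 were outside it under some fixed alternative. In classes under 15 CPM the S100a4 ratio rested on few UMIs, and with doublets kept it stayed within its interval only in alveolar macrophage-like cells. The setting of at least 500 genes gave no value for interstitial macrophage-like lists and genes, since under 100 such cells were named in a library. For values that moved or changed sign, the cause was not tested.

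With each library clustered alone, share folds were 0.866 for neutrophil-like, 0.972 for fibroblast-like, 1.12 for classical and 1.65 for nonclassical monocyte-like, 1.84 for immature granulocyte-like and 0.452 for interstitial macrophage-like cells (0.452 with dendritic cells). They were 1.47 for all monocytes and 0.842 for fibroblasts with pericytes. Among immune cells only, folds were 0.858 for neutrophil-like, 1.53 for B cell-like, 1.06 for T cell-like, 0.681 for alveolar macrophage-like, 1.08 for classical and 1.21 for nonclassical monocyte-like and 1.31 for NK cell-like cells. They were 0.842 for neutrophils with immature granulocytes, 1.13 for all monocytes and 1.31 for all lymphocytes. Log2 ratios of S100a4 with doublets kept were 0.20 in endothelial-like, 1.29 in neutrophil-like, 0.35 in fibroblast-like, -0.17 in T cell-like, 2.05 in immature granulocyte-like, 0.12 in B cell-like and -0.029 in type 2 alveolar epithelial-like cells; all but those of endothelial-like and immature granulocyte-like cells changed sign. With every cell weighing the same they were 0.26 in all cells and 0.20 in interstitial macrophage-like cells (a change of sign), and at Leiden resolution 2 they were -0.40 in the latter. The difference in the share of cells with an S100a4 UMI was 1.28 points in T cell-like cells and 0.686 points in all cells after thinning, and 0.443 points in T cell-like cells with doublets kept. Among genes called higher or lower, log2 ratios that changed sign with doublets kept were -0.70 for Igha in B cell-like cells, -0.15 for Cxcl2, -0.037 for Il1b, -0.50 for S100a8 and -0.53 for S100a9 in fibroblast-like cells, and -0.14 for S100a8 in T cell-like cells, which was -0.10 with every cell weighing the same. At Leiden resolution 2, Il12b in interstitial macrophage-like cells was at 2.51, a change of sign. List medians there were 0.22 (NF-kB), 0.0063 (MHC class II) and -0.049 (complement and scavenger). Under TMM scaling, list medians were -0.038 (S100 family), -0.094 (niche factors), 0.050 (factors responding to S100A4), 0.050 (stress), 0.87 (haemoglobin) and -0.67 (surfactant) in all cells. Others were -0.11 (S100 family), -0.048 (suppressive genes) and 0.022 (NF-kB) in neutrophil-like cells, 0.12 (MHC class II) and 0.17 (stress) in B cell-like cells, 0.11 (cytotoxic) in NK cell-like cells. Under median-of-ratios scaling, list medians were -0.033 (S100 family), -0.089 (niche factors), 0.055 (factors responding to S100A4), 0.055 (stress), 0.88 (haemoglobin) and -0.67 (surfactant) in all cells. Others were -0.11 (S100 family), -0.044 (suppressive genes) and 0.027 (NF-kB) in neutrophil-like cells, 0.12 (MHC class II) and 0.17 (stress) in B cell-like cells, 0.13 (cytotoxic) in NK cell-like cells. With at least 500 genes, list medians were 1.02 (haemoglobin) in all cells, 0.012 (cytotoxic) in NK cell-like cells. With doublets kept, list medians were -0.21 (proliferation) and 0.027 (stress) in all cells, 0.11 (granule genes) and 0.036 (NF-kB) in neutrophil-like cells, -0.47 (type I interferon), 0.0028 (MHC class II), 0.043 (activation) and 1.65 (haemoglobin) in B cell-like cells. Others were -0.10 (S100 family) and -0.084 (matrix) in fibroblast-like cells, -0.15 (S100 family), -0.043 (naive and memory), 0.73 (proliferation) and -1.37 (haemoglobin) in T cell-like cells. Others were 0.22 (NF-kB) and -0.13 (MHC class II) in interstitial macrophage-like cells. With every cell weighing the same, list medians were -0.11 (S100 family), -0.050 (factors responding to S100A4), 0.057 (stress), 0.44 (haemoglobin) and -0.76 (surfactant) in all cells, -0.15 (type I interferon) in endothelial-like cells. Others were 0.058 (activation) in B cell-like cells, -0.073 (S100 family), 0.019 (interferon-gamma), -0.10 (cytotoxic), 0.32 (proliferation), 0.14 (stress) and 0.71 (haemoglobin) in T cell-like cells. Others were -0.43 (type I interferon) and -0.16 (MHC class II) in classical monocyte-like cells, 0.0043 (cytotoxic) in NK cell-like cells, -0.21 (NF-kB) and -0.12 (MHC class II) in interstitial macrophage-like cells. With at least 100 UMIs per gene, list medians were 0.042 (factors responding to S100A4) in all cells. Without a filter on low counts, list medians were -0.070 (S100 family) in all cells, 0.18 (activation) in endothelial-like cells, -0.071 (proliferation) in neutrophil-like cells, -0.033 (chemokine receptors) in B cell-like cells, -0.086 (S100 family) in fibroblast-like cells, -0.066 (S100 family) in T cell-like cells. Others were -0.17 (complement and scavenger) in alveolar macrophage-like cells. With totals lacking mitochondrial, ribosomal and haemoglobin genes, list medians were -0.050 (S100 family), 0.037 (factors responding to S100A4), 0.037 (stress) and -0.68 (surfactant) in all cells.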

Other observations

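The lists read in every compared class, the mitotic gene sums, the genes followed across classes and the tests of free RNA, scaling, structural cell recovery and blood were chosen after the result was seen. The interferon-gamma and MHC class I list lay below the middle 95% of random lists in 7 of 13 classes and above it in none. Its median log2 ratio was -0.55 in pericyte or smooth muscle cell-like, -0.41 in type 2 alveolar epithelial-like, -0.38 in neutrophil-like, -0.33 in immature granulocyte-like and -0.26 in nonclassical monocyte-like cells, beside the endothelial-like and classical monocyte-like cells already described. It was 0.05 in B cell-like and -0.06 in NK cell-like cells. Cluster mix may enter the pericyte or smooth muscle cell-like value. Cluster 17, where more endothelial markers were detected, held 57.4% of that class in the IgG library and 48.8% in the S100A4-11 library. The type I interferon list lay below that range in 3 of 13 classes, the third being immature granulocyte-like cells at -0.24. Dissociation stress genes lay below it in 2 classes (endothelial-like, and alveolar macrophage-like at -0.14). They lay above it in 6, among them immature granulocyte-like cells at 0.30 and classical monocyte-like cells at 0.16. Hypoxia and glycolysis genes lay below it in 3 classes (neutrophil-like, classical monocyte-like, and immature granulocyte-like at -0.20) and above it in 3, fibroblast-like (0.15), T cell-like (0.11) and alveolar macrophage-like cells (0.07).

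Proliferation genes lay below the range of random lists in 6 of 12 classes and above it in T cell-like cells. In endothelial-like cells 11 mitotic genes summed to 74.2 CPM (70.2 to 78.4) in the IgG library and 6.45 CPM (5.16 to 7.97) in the S100A4-11 library, 11.5-fold lower. Cells with UMIs of at least 4 of these genes numbered 14 of 3208 and 2 of 2627, and 5 cells held 66.1% of the IgG UMIs, so few dividing cells set this value. In alveolar macrophage-like cells the sum was 324 CPM (310 to 339) and 168 CPM (156 to 181), from 32 of 707 and 13 of 493 such cells. In T cell-like cells it was 223 CPM (207 to 239) and 374 CPM (355 to 394), from 10 and 15 such cells. The reporter row EYFP in the matrices held 0 UMIs in both libraries.

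Type I interferon genes lay below random lists in neutrophil-like cells of the S100A4-11 library. A different mix of the neutrophil clusters at Leiden resolution 1 was argued against. The list lay below random lists within both of the largest, at -0.34 and -0.58 with percentile 0 in each. A different mix of cell states within those clusters was not tested and stays open. Free RNA of other cells was argued against as well: the median member's IgG level in neutrophil-like cells was 55.1% of its highest class, above the 20% that marked genes attributable to free RNA. Lower interferon exposure of neutrophils with the antibody, and a difference between animals or captures, may each account for it and stay open with 1 library per group.

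Zbtb16, Fkbp5 and Tsc22d3, all glucocorticoid-induced, had intervals below a ratio of 1 in 9, 5 and 9 of 13 classes. Not all were past 1.5-fold, and the lowest log2 ratio of Tsc22d3 was -0.476. These genes were picked after many genes had been viewed. Scaling was argued against for Zbtb16 in endothelial-like cells, where the median log2 ratio of all genes was -0.013 and TMM scaling shifted log2 ratios by 0.015. Fkbp5, Tsc22d3 and other classes were not compared in this way. Lower glucocorticoid signalling at collection stays open. Other glucocorticoid-induced genes lay at percentile 21.3 of random lists in endothelial-like cells and 24.3 in fibroblast-like cells, where an exclusion had been foreseen. By the rule set beforehand this argued against lower glucocorticoid signalling. Members went both ways, however (5 above and 9 below 0 in each class). Medians over such members were taken to decide nothing, a limit not set beforehand and applied to these genes only. Other lists with members on both sides were described by their medians. An example is the interferon-gamma list in classical monocyte-like cells (7 above and 13 below 0). In pericyte or smooth muscle cell-like and type 2 alveolar epithelial-like cells these genes lay below random lists, at percentiles 0.310 and 0.740. In immature granulocyte-like cells they lay above them, at 99.9. Members went both ways there too (5 above and 9 below 0, 4 and 7, and 5 and 2, in that order), so these medians decide nothing either. A treatment effect and a difference between animals or captures stay open too. AY036118, Gphn and Gm11808 had intervals above a ratio of 1 in 13 of 13 classes, not all past 1.5-fold (log2 ratios of AY036118 were 0.113 to 0.482). This could likewise reflect the capture rather than the antibody.

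B cell-like and NK cell-like cells were a larger share and structural cells a smaller share of the S100A4-11 library. Fewer structural cells recovered, and nothing else, was argued against: among immune cells the B cell-like fold was still 1.53, while the neutrophil-like fold was 0.858. More blood left in the lung, and nothing else, was tested by the neutrophil-like fold over all cells, which was 1.0. That test assumed that blood adds neutrophil-like and B cell-like cells alike, which was not measured, so it cannot decide. Haemoglobin was 0.0522% of IgG and 0.107% of S100A4-11 UMIs. More blood left in the lung, a mixture of it with fewer structural cells recovered, an effect of the antibody on lung lymphocytes, and a difference between animals stay open. An effect on lymphocytes is therefore a possible explanation that these libraries did not test.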
